A study of Mus musculus with 2 samples.

How the data were processed

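Each of the 2 groups was 1 pool of livers from 5 male mice, and each pool was measured on 1 array, so each group had 1 replicate. Per the labels, the mice received 1e9 plaque forming units of virus at 8 weeks of age, and labelled RNA was made from 0.5 micrograms. The labels' protocols give collection 2 weeks after injection for both groups, but the description of the Ad-378 pool says 3 weeks, and this could not be settled. The labels' extraction protocol describes a kit for blood RNA with removal of globin transcripts, although the tissue is given as liver.

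The arrays were Agilent 1-colour expression arrays with 44397 spots, of which 1377 were controls. The deposited scanner values are spot intensities on a linear scale, and per the file headers the processed signal had been background-subtracted and detrended within the array, with no scaling between arrays. Flags for background, saturation and outliers, which are other values of 0 or 1, are also deposited. The submitters' processing notes name Agilent Feature Extraction 9.1, whereas the file headers give version 11.0.1.1. The deposited series matrix holds intensities that equal the raw median signal of each array in 100% of values, with no background subtraction, log or scaling, and column medians of 103 (Ad-Ctrl) and 95 (Ad-378). Its direction follows from that equality.

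Control spots and spots marked as outliers (123 gene spots per array) were left out. The main value was log2 of the processed signal minus the 75th percentile of the array, a signal of 800 in Ad-Ctrl and 695 in Ad-378. Spots of a probe were averaged, and a probe was called well above background where most of its unmarked spots were. Of 39401 probes, 27219 carried a gene symbol (20652 symbols) and 12182 did not. The files give transcript identifiers and no symbols, so a probe was named where its identifier matched, without versions, a single gene of a RefSeq table of assembly GRCm38.p6. No coordinates are given, since the headers name build mm9. A gene took the value of its brightest probe well above background on both arrays. Of 3419 genes with 2 or more such probes, 927 had probes of opposite sign and 148 had probes over 1 log2 unit apart. A gene well above background on 1 array only has a lower bound of its fold, the bright array's value against the higher of the dimmest detected signal and the probe's own on the other array.

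The scanner error of a difference was taken from the deposited error of both spots, with a median of 0.20 log2 units. It covers measurement on the array only. Probes printed in 10 spots had a median SD of log2 signal of 0.062 in Ad-Ctrl (279 probes) and 0.066 in Ad-378 (286 probes). The number of arrays limits the precision. Both arrays carry 1 scan identifier, so no scan batch could be tested.

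No test was run between the groups. Genes were counted at a 2-fold difference. Before the data were examined, 35 gene lists were fixed, and each list needs 5 measured genes. A list's median was set against 10000 random lists of the same size matched on mean signal in 20 bins. Its percentile describes these 2 arrays only. Bootstrap intervals of the medians (2000 resamples of members) describe spread among genes, not mice. The limits of 2.5 and 97.5 for standing apart, the 20 bins, the lowess span of 0.3, the averaging of spots, the bootstrap intervals and the 95% range of the scanner error beyond which a gene's value counts as moved were set after the data had been opened. Lists share some genes, such as Cyp7b1 and Slco1a1.

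The genes named were fixed by a rule set before the data were examined. They are 16 genes of bile acid, cholesterol, thyroid hormone and miR-378 biology in every case, the 12 highest and 12 lowest genes whose probes had 1 sign, up to 4 members of each list with the largest differences, and up to 5 genes per direction detected on 1 array. Genes named outside it were chosen after their values were seen. Some genes that the rule names are not reported here, singly or in the plots of single genes, and they stay in the counts and list medians.

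The alternatives were quantile normalization, loess normalization of difference on mean, the 75th percentile over probes well above background on both arrays, the mean over probes, the series matrix values, no filter on background, and thresholds of 1.5-fold and 3-fold. After the data had been seen, normexp background correction (offset 50) on the median signal and lists without shared genes were added. The steps were tested on simulated data for this comparison over 14288 genes. Of genes planted at a log2 difference of 1.5, 99% were recovered, and at 2.5, 100%. Of unchanged genes 0.0568% passed the threshold, and 5% of unchanged lists lay outside the central range. The simulated noise was the scanner error alone, without spread between pools or correlation among genes. These rates therefore do not describe how often 2 pools of mice would differ. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. Seed matches of miR-378 were not analysed here, as no transcript sequences were used.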

Results

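Liver RNA was compared between male mice given a control adenovirus (Ad-Ctrl) and male mice given an adenovirus labelled as overexpressing the microRNA miR-378 (Ad-378). Each group was 1 pool of the livers of 5 mice, injected through the tail vein at 8 weeks of age, and was hybridised to 1 array. The title of the study asks how miR-378, described there as responsive to thyroid hormone, relates to bile acid synthesis and cholesterol in the liver. Of 43020 gene spots per array, 27161 (63.1%) were well above background in the Ad-Ctrl pool and 28262 (65.7%) in the Ad-378 pool, and no spot was saturated. A gene level could be set on both arrays for 14288 genes, whose log2 signals correlated at r = 0.980 across genes, which are not independent replicates. With 1 array per group there was no replicate spread, so no difference below has a replicate check, and no p-value is given. All log2 differences are Ad-378 minus Ad-Ctrl.

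On the main values, Moxd1, Acod1 and Il6 were the genes furthest above in the Ad-378 pool, and Sult2a1, Sult2a2 and Serpina7 those furthest below. Of the 14288 genes, 405 were at least 2-fold higher in the Ad-378 pool and 645 at least 2-fold lower, together 7.35% of genes. Moxd1 is a copper monooxygenase related to dopamine beta-hydroxylase, and had a log2 difference of 6.46. It was followed by Acod1 (4.94), which makes itaconate in activated macrophages, the cytokine gene Il6 (4.24), the steroid dehydrogenase gene Hsd3b5 (4.05) and Nos2 (3.87), the inducible nitric oxide synthase. The rest of the 12 highest genes were AA467197 (3.64), the chemokine genes Ccl4 (3.59) and Ccl3 (3.09), the pattern recognition receptor Clec4e (3.46), the fatty acid receptor Gpr84 (3.12), Cd40 (2.92) and the cholesterol 25-hydroxylase Ch25h (2.84).

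The lowest genes were the hydroxysteroid sulfotransferases Sult2a1 (-5.24) and Sult2a2 (-5.02), the thyroxine-binding globulin gene Serpina7 (-4.24) and the estrogen sulfotransferase Sult1e1 (-4.14). The calcium-binding protein gene S100g (-4.01), Pcdh20 (-3.84), the noncoding RNA Lockd (-3.83), Sprr1a (-3.81), Tlcd3a (-3.79), Tceal5 (-3.77), Fndc10 (-3.76) and the DNA polymerase gene Polh (-3.71) completed the 12 lowest. The Sult2a genes are near-identical copies, so their probes may not tell them apart. On the deposited values without background subtraction the differences of dim genes were smaller, at 4.95 for Moxd1 and -3.12 for Sult2a1. After normexp they were 1.99 for AA467197, 2.47 for Nos2, -1.65 for Polh, -1.85 for Pcdh20, -1.99 for Tceal5 and -2.02 for Lockd. Il6 (2.82), Sult2a2 (-2.96) and S100g (-2.42) were also smaller in size after normexp. On the series matrix values Serpina7 (-3.59) lay below Sult2a2 (-3.39) and Sult2a1 (-3.12). The sizes and ranks of these genes thus depended on the setting. Both settings use the raw median signal in place of the processed signal, so an effect of background alone was not tested apart.

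**Figure D1:**
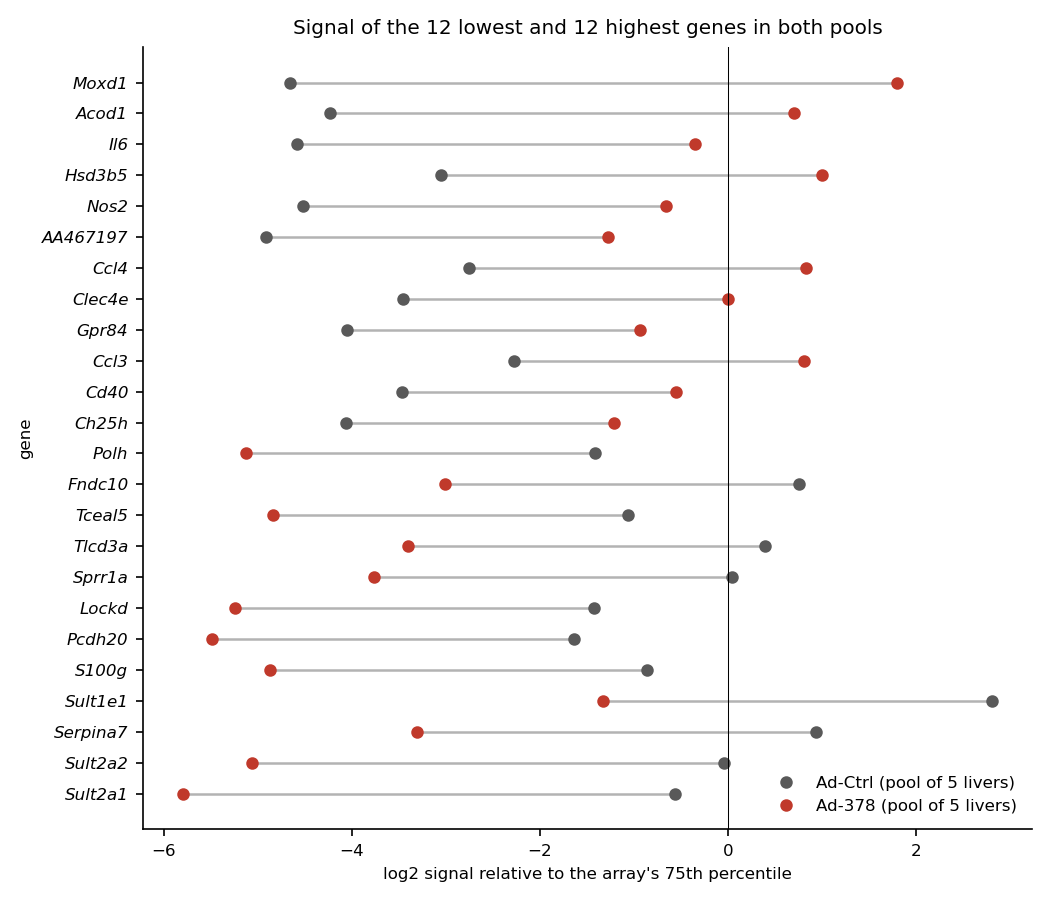
Log2 signal relative to the 75th percentile of each array (x axis) of the 12 highest and 12 lowest genes (y axis), with a grey point for the Ad-Ctrl pool and a red point for the Ad-378 pool. Moxd1 lies 6.46 apart at the top and Sult2a1 -5.24 at the bottom, and there is no error bar because each pool was measured on 1 array.

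Further genes were above background in 1 pool only. In the Ad-378 pool alone, 722 genes were well above background, 106 of them with a bound of at least 2-fold, and Tnf, the tumour necrosis factor gene, was at least 19.6-fold higher than in Ad-Ctrl. Ptgs2, the inducible cyclooxygenase, was at least 18.2-fold higher, Inhba at least 7.83-fold, the chemokine gene Ccl12 at least 7.72-fold and Lad1 at least 7.26-fold. In the Ad-Ctrl pool alone, 338 genes were well above background, 127 of them with a bound of at least 2-fold. Among these, Cntnap2 was at least 36.6-fold higher in Ad-Ctrl, the olfactory receptor gene Olfr1264 at least 19.9-fold, Sult2a4 at least 15.2-fold, Sult2a6 at least 12.4-fold and Tpte at least 9.84-fold. All bounds rest on the main values and were not computed under the other settings. On the series matrix values and after normexp the dim genes above had smaller differences, so the bounds may not hold there.

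Bile acid synthesis genes lay unevenly between the pools. Cyp7a1, the rate-limiting enzyme of the classical pathway, had a log2 difference of -0.40, with a scanner error of 0.20. Cyp8b1, the sterol 12-alpha-hydroxylase of cholic acid synthesis, was higher in Ad-378 by 1.61, and Cyp7b1, the oxysterol 7-alpha-hydroxylase of the alternative pathway, by 1.71, while Cyp27a1 differed by 0.12 and by -0.01 under loess normalization. Of 17 members of the bile acid synthesis list, 4 were at least 2-fold higher and 0 at least 2-fold lower, among them Ch25h (2.84) and the cholesterol 24-hydroxylase Cyp46a1 (2.83-fold higher). The list median of 0.34 lay at percentile 98.16 of random lists, but the median was 0.13 under both quantile normalization (percentile 87.90) and loess (91.24), so its standing apart from other genes depended on the scaling.

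Bile acid transport and signalling genes were mostly lower in the Ad-378 pool, 11 of 16 members having a negative difference and the list median being -0.26 (percentile 0.32). Nr0b2, the small heterodimer partner that represses Cyp7a1, was lower by a log2 difference of -1.42, and the basolateral exporter subunit Slc51b by -1.03. After normexp Nr0b2 lay just inside 2-fold and Slc51b at -0.52. Slc51a, also of this list but not among the 16, was well above background in the Ad-378 pool only. It was dim there, with a log2 signal of -5.39. The uptake transporter Slco1a4 had -0.85, whereas Slco1a1, also a male-biased gene, was higher at 2.44. The bile acid receptor gene Nr1h4 differed by 0.49. The bootstrap interval of this median, -0.45 to 0.07, included 0.

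Cholesterol synthesis genes were modestly higher in the Ad-378 pool. The list median was 0.34 over 24 members (percentile 99.94; bootstrap interval 0.12 to 0.60), with 4 members at least 2-fold higher and 0 lower. Those 4 were Hsd17b7 (1.42), Insig1 (1.25), Stard4 (1.13) and Tm7sf2 (1.04), of which Insig1 (0.93), Stard4 (0.93) and Tm7sf2 (0.97) lay inside 2-fold after normexp. Stard4 (0.96) and Tm7sf2 (0.98) did so on the series matrix values too, as did Stard4 with the mean over probes (0.75) and Tm7sf2 under quantile normalization (0.96), loess (0.92) and the other 75th percentile. The sterol exporters Abcg5 and Abcg8 had differences of -0.48 and -0.32.

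**Figure D2:**
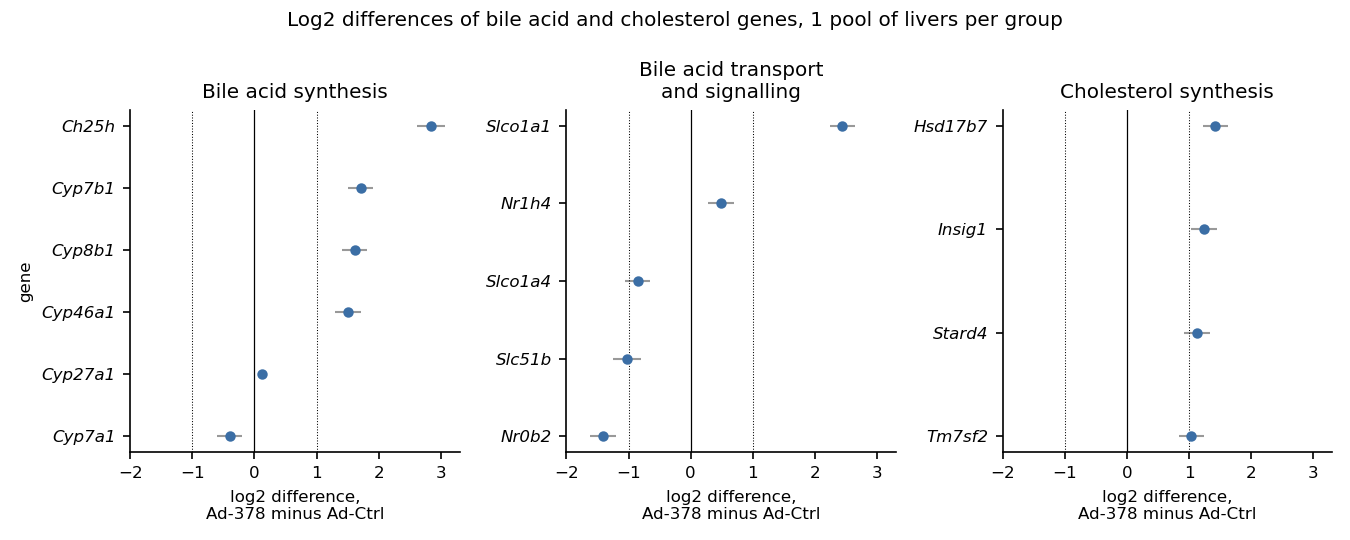
Log2 difference, Ad-378 minus Ad-Ctrl (x axis), of the named genes (y axis), chosen mostly for the largest differences, in the bile acid synthesis, bile acid transport and cholesterol synthesis lists, with the scanner error of 1 array per pool as a grey line and dotted lines at 2-fold. Cyp8b1 (1.61) and Cyp7b1 (1.71) lie beyond 2-fold while Cyp7a1 (-0.40) does not, and Nr0b2 (-1.42) is the lowest transport and signalling gene shown.

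Genes reported as targets of miR-378 were mostly lower in the Ad-378 pool. Of 13 members, 10 had a negative difference, and the median was -0.29 (percentile 2.18); the percentile was 3.32 with the mean over probes and 2.84 with no filter on background, and without genes shared with other lists the median was -0.44. Med13, a Mediator subunit, differed by -1.79 and Grb2, a growth factor signalling adaptor, by -0.87, whereas Crat, a carnitine acetyltransferase, was higher by 1.21. Med13 and Crat were dim, and on the values after normexp they differed by -0.76 and 0.48. Mafg, a small Maf transcription factor, had -0.10, with its 3 probes between -0.10 and 0.10. Ppargc1b, the gene that hosts miR-378, had a difference of -0.00, which does not check the product of the virus.

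Among genes that respond to thyroid hormone, the deiodinase gene Dio1 differed by 0.95 and Gpd2, a mitochondrial glycerophosphate dehydrogenase, by 0.98. The receptor gene Thra differed by 1.00 at its brighter probe and 0.28 at another, and Thrsp, a lipogenic regulator, by -0.06. The median of the 13 measured members was 0.05 (percentile 45.41), with 0 members at least 2-fold apart.

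Fatty acid oxidation genes were higher in the Ad-378 pool nearly throughout. Of 25 members, 24 had a positive difference and 6 were at least 2-fold higher, including the hormone gene Fgf21 (2.04), the peroxisomal thiolase gene Acaa1b (1.48), Vnn1 (1.43) and the thioesterase gene Acot1 (1.36). Their median was 0.55 (percentile 100; bootstrap interval 0.48 to 0.81). The median was 0.37 under loess. Oxidative phosphorylation genes were higher by less, with a median of 0.42 (percentile 99.98), which was 0.26 under quantile normalization and 0.25 under loess. Of 27 members, 26 had a positive difference and 0 were at least 2-fold apart, and 14 of 15 hepatocyte genes were positive too. The list was led by Ndufb8 (0.64), Ndufv1 (0.59) and Uqcrfs1 (0.58).

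Male-biased liver genes were higher and female-biased ones lower in the Ad-378 pool. Of 14 male-biased genes, 6 were at least 2-fold higher and 0 lower, with a median of 0.95 (percentile 100; bootstrap interval 0.26 to 1.71). Hsd3b5 (4.05), Slco1a1 (2.44), the fatty acid elongase gene Elovl3 (2.37) and Cyp7b1 (1.71) differed most. Of 10 female-biased genes, 4 were at least 2-fold lower and 1 higher, with a median of -0.82 (percentile 0.03; bootstrap interval -3.26 to -0.07). Sult2a1 (-5.24), Sult1e1 (-4.14) and Cyp2b9 (-1.20) were among the lowest.

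Proliferation genes were far lower in the Ad-378 pool. Of 23 members, 19 were at least 2-fold lower and 0 higher, and the median of -2.04 (bootstrap interval -2.15 to -1.61) lay below all 10000 random lists. The mitotic genes Cdc20 (-2.93), Aurka (-2.66) and Cdk1 (-2.56) and the replication licensing gene Mcm6 (-2.51) were the lowest.

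Markers of stellate cells, macrophages, T and NK cells and sinusoidal endothelium were lower as well, whereas those of cholangiocytes (median 0.35) and B and plasma cells (0.39) were not. All 14 measured stellate cell and fibroblast markers had a negative difference, with a median of -0.80 (percentile 0; -0.51 after normexp) and the collagen genes Col3a1 (-2.71), Col1a1 (-2.22) and Col1a2 (-1.63) and the proteoglycan gene Lum (-1.94) lowest. All 15 Kupffer cell and macrophage markers were lower too, with a median of -0.88 (percentile 0; bootstrap interval -1.04 to -0.72), including Gpnmb (-1.25), Cd5l (-1.12), Trem2 (-1.06) and Adgre1 (-1.04). The median of antigen presentation genes was -0.39 (percentile 0.08; -0.59 under loess), with 4 of 12 at least 2-fold lower, namely H2-Eb1 (-1.25), Cd74 (-1.22), H2-Aa (-1.17) and H2-Ab1 (-1.16). This list was split, since 4 of the 12 had a positive difference, among them Tap2 (0.36) and Tap1 (0.19). T and NK cell markers had a median of -0.38 (percentile 0.64; -0.24 after normexp), with Gzma (-1.33), Gzmb (-1.25) and Cd8a (-1.14; -0.68 after normexp) lowest among 17. The bootstrap intervals of the antigen presentation (-1.17 to 0.02) and T and NK cell (-0.55 to 0.02) medians included 0. Sinusoidal endothelial markers differed less, with a median of -0.20 over 14 genes (percentile 1.66, and 2.58 on the deposited series matrix values), and none of them was 2-fold apart. Hepatocyte genes had a median of 0.23 (percentile 54.73), which was 0.02 under quantile normalization and 0.00 under loess.

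**Figure D3:**
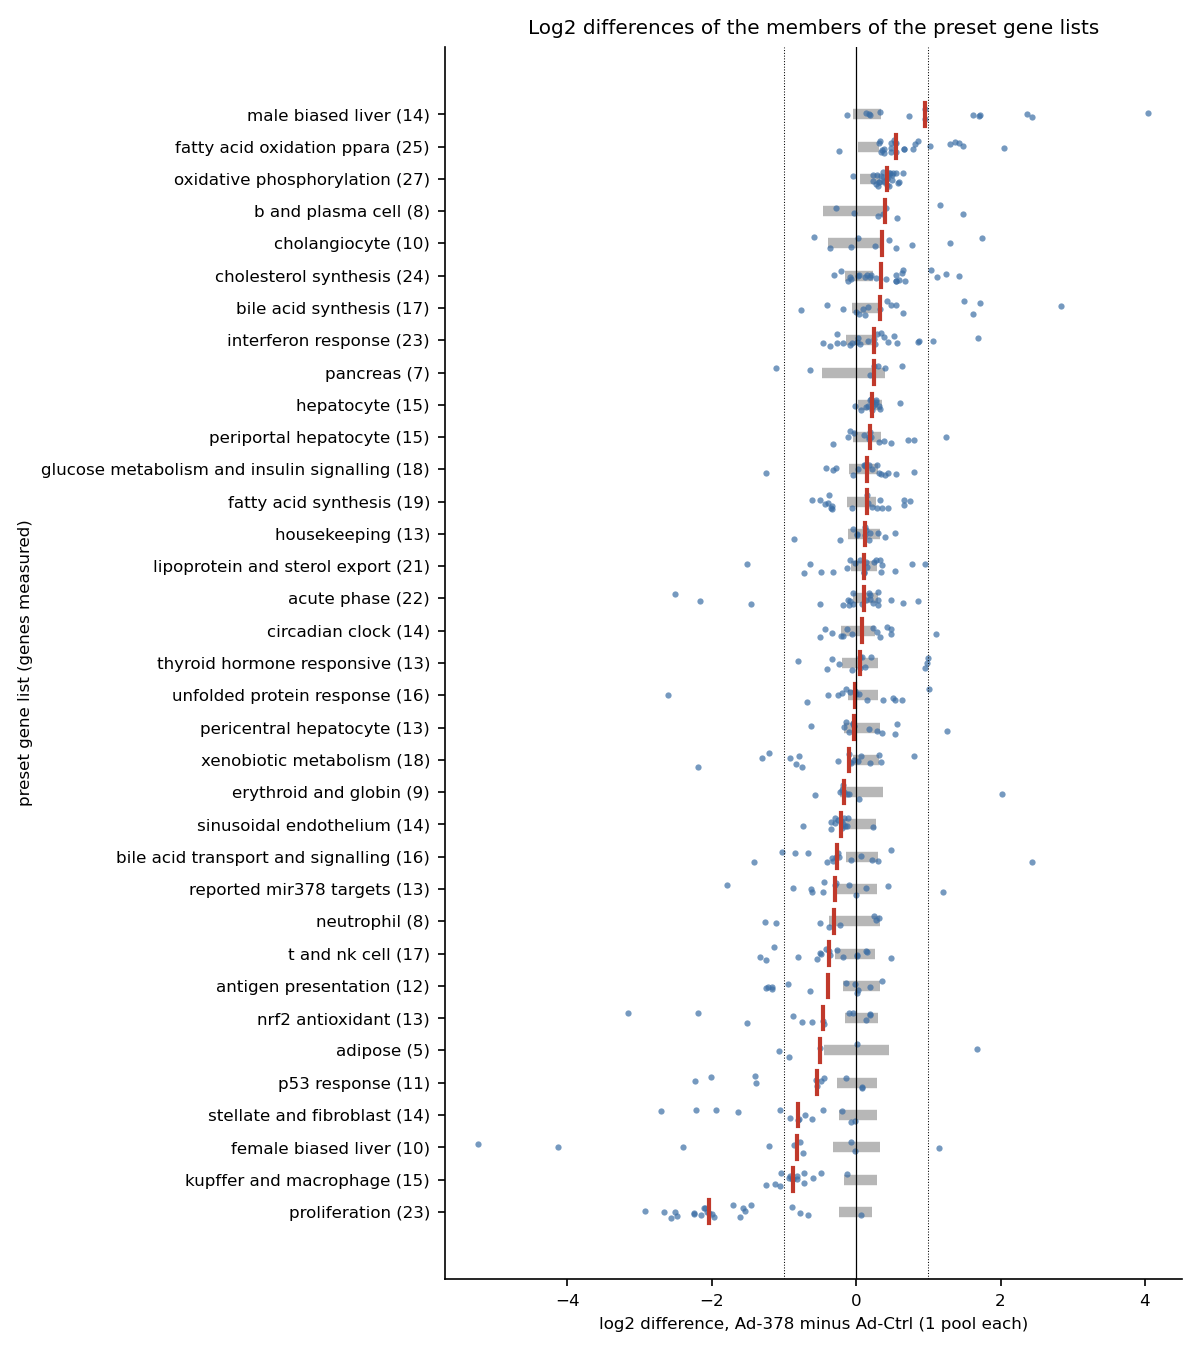
Log2 difference, Ad-378 minus Ad-Ctrl (x axis), of the members of each preset list (y axis, with the genes measured), with a blue point per gene, a red bar at the list median, a grey band for the central 95% of medians of matched random lists and dotted lines at 2-fold. Proliferation has the lowest median (-2.04) and male-biased genes the highest (0.95).

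Genes of the Nrf2 and p53 responses were lower in the Ad-378 pool. The antioxidant list of Nrf2 targets had a median of -0.46 (percentile 0) with 3 of 13 members at least 2-fold lower, these being the carbonyl reductase Cbr3 (-3.16), the glutathione transferase Gstm3 (-2.19) and the quinone oxidoreductase Nqo1 (-1.51). The p53 response list had a median of -0.54 (percentile 0.11) with 4 of 11 at least 2-fold lower: Gdf15 (-2.24), Zmat3 (-2.01), Phlda3 (-1.40) and Trp53inp1 (-1.39). The other probe of Trp53inp1 had -0.64, inside 2-fold. Xenobiotic metabolism genes had a median of -0.09 (percentile 0.78; -0.25 under loess; bootstrap interval -0.79 to 0.04) with 3 of 18 at least 2-fold lower, among them Cyp2c55 (-1.31). Interferon response genes had a median of 0.25 over 23 members (percentile 98.45), with Ifit1 (1.69) and Isg15 (1.06) at least 2-fold higher, but after normexp the median was 0.15 and the percentile 87.96.

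In all, 20 of the 35 lists lay outside the central 95% of random lists, 7 above and 13 below. By chance 1.75 would, if the genes of a list varied independently of each other. Random lists carry no such shared variation, so the count by itself does not show a difference between the groups. Of the 20 lists, 14 stayed outside under each alternative that was run. The bile acid synthesis, reported target, interferon, endothelial, B cell and adipose lists did not. The acute phase list had a median of 0.11 and a mean of -0.15, with 3 of 22 members at least 2-fold lower, the lipocalin Lcn2 (-2.51), Orm3 (-2.16) and Steap4 (-1.46). Fatty acid synthesis genes had a median of 0.14, lipoprotein and sterol export genes 0.11, circadian clock genes 0.09, housekeeping genes 0.12 and unfolded protein response genes -0.01, and the sign of each of these and of the acute phase median turned under at least 1 other setting. Single members of these lists did differ: the sterol exporter Abcg1 had -1.51, the unfolded protein response gene Chac1 -2.60 and the clock output gene Dbp 1.11. Asns, also of the unfolded protein response list, had 1.02, which lay inside 2-fold under quantile normalization (0.97). Glucose metabolism genes had a median of 0.15, with the glycogen synthase gene Gys2 at 0.80. Periportal hepatocyte genes had a median of 0.19, with Pigr at 1.25, and under loess both of these medians were 0.01. Pericentral genes had a median of -0.03, with Slc22a3 at 1.26 (0.92 after normexp), the sign of the pericentral median also turning with the setting.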

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

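The check of probes without a gene symbol was set by a rule, and no explanation of it was tested. Of the 5534 probes without a symbol that were well above background on both arrays, 265 were at least 2-fold higher in the Ad-378 pool and 106 at least 2-fold lower. They stand here because the comparison of named genes does not use them. Their log2 differences ran from -3.89 to 2.92, with a median of 0.17.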

How the results depend on the processing

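The normexp background correction and the lists without shared genes were chosen after seeing the data. No paired analysis was possible because each group holds only replicate 1. Not run were spike-in scaling, since the spike-in probes lay near background (highest median signal 26.2), normexp on the mean signal, which is not used here, and every seed-match result. Genes at least 2-fold higher and lower numbered 222 and 394 on the series matrix values, 200 and 353 after normexp, and 1059 and 1164 with no filter on background, where dim probes enter. At 1.5-fold they numbered 1256 and 1721, and at 3-fold 106 and 201. The cause of the lower counts on the matrix values and after normexp was not tested. Quantile and loess normalization moved the medians of bright lists: fatty acid oxidation to 0.37 and 0.37, oxidative phosphorylation to 0.26 and 0.25, hepatocyte genes to 0.016 and 0.0030, housekeeping genes to -0.031 and -0.039, pericentral genes to -0.11 and -0.14 and erythroid genes to -0.28 and -0.29. The proliferation median was -1.58 on the matrix values and -1.44 after normexp. The cause was not tested. Of 260 list medians under the alternatives, 246 lay inside the bootstrap interval of the main median and 14 outside it. That interval is wide for some lists (adipose -1.06 to 1.68), so lying inside it does not show a stable median. The bile acid synthesis median of 0.13 under loess, for example, counted as inside. Of 996 values of named genes, 924 moved by less than the 95% range of the scanner error and 72 by more, and of the named genes at least 2-fold apart 0 changed sign. Cyp27a1 and Ppargc1b, both near 0, did. The share of higher among 2-fold genes was 38.6%, between 33.1% and 38.8% under other scalings and 47.6% with no filter. Depth on an array is signal over background, which limits the dim genes most.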

Other observations

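The 10 cholangiocyte markers had a median log2 difference of 0.35 (percentile 97.29; 0.20 after normexp), with the chloride channel gene Cftr at 1.75 (0.87 after normexp), Spp1 at 1.30 and Sox9 at 0.78. The 8 B and plasma cell markers had a median of 0.39 (percentile 98.23, 95.22 with no filter on background), led by the joining chain gene Jchain (1.47) and Ms4a1 (1.17; 0.47 after normexp). The 8 neutrophil markers had a median of -0.30 (percentile 5.54; -0.15 after normexp). Mpo had -1.26 and Mmp8 -1.11, but these were -0.12 and -0.23 after normexp. The 9 erythroid and globin genes had a median of -0.16 (percentile 4.92), although Alas2, the erythroid heme synthesis enzyme, was at 2.02. The 5 adipose genes had a median of -0.50 (percentile 1.68, 4.80 with no filter on background, where the median was -0.26; bootstrap interval -1.06 to 1.68), with Cfd at -1.06 (-0.48 after normexp) and Cidec at 1.68. The 7 exocrine pancreas genes had a median of 0.24 (percentile 85.15; 0.04 with no filter on background), with Cela2a at -1.11 (-0.32 after normexp) and Ctrb1 at 0.63.

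In the weighing that follows, the 3 tests of the proliferation pattern and the macrophage test were chosen only after the result was seen.

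Proliferation genes were lower in the Ad-378 pool, and 3 explanations were weighed. Scaling of the arrays may shift all genes, but the median nearest to 0 under any other normalization was still -1.44. A smaller share of all cells other than hepatocytes could lower every such marker alike. The endothelial median, however, lay 0.68 above the macrophage median (bootstrap interval 0.48 to 0.77). This argues only against an equal loss of all such cells, and a loss of particular cell types stays open and was not tested. A later collection of the Ad-378 pool, at 3 weeks by its description, cannot be told apart from the virus, since 1 pool stands for each. An effect of the virus product on dividing cells also stays open and was not tested.

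Male-biased genes were higher and female-biased genes lower in the Ad-378 pool, although the labels give male mice in both. Female mice in the Ad-Ctrl pool could produce part of this and cannot be told apart from the virus: the Y-linked genes Ddx3y (0.31), Eif2s3y (0.43) and Uty (0.39) were higher in Ad-378, their median of 0.39 was above the limit of 0.3 set beforehand, and the 2 Xist probes, at most -7.44 in Ad-Ctrl, were not above background in either pool, which leaves open whether they respond. Females would lower a male-biased gene no more than a Y-linked one, and the male-biased median of 0.95 lay above the Y-linked 0.39. Its interval (0.26 to 1.71) includes that value, but describes spread among genes, so it cannot decide for single genes. Female-biased genes, which females would raise in Ad-Ctrl, went both ways. Of 10, 4 were at least 2-fold lower in Ad-378, whereas Cyp2b13 (-0.07) and Cyp3a44 (-0.02) hardly differed. Shared hybridization among Sult2a copies stays open for Sult2a1, since only 1 of the 10 measured female-biased genes is such a copy and leaving it out (median -0.78, percentile 0.03) could hardly move the list. A response of sex-biased genes to the virus product also remains possible and was not tested.

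Il6, Nos2 and Tnf, picked from the top of the ranking, were higher in the Ad-378 pool beside lower macrophage markers, while 0 of 22 acute phase genes were at least 2-fold higher and 3 were lower, and the neutrophil median was -0.30. More macrophages bearing the listed markers are an unlikely cause, since the macrophage median was -0.88 (bootstrap interval -1.04 to -0.72). The list cannot decide about macrophages that carry few of these markers. Faults of single spots are unlikely for Il1b and Acod1, each printed in 10 spots, whose lowest spot-pair difference was 2.17, but Il6 and Nos2 rest on 1 spot each. A wider response of NF-kB targets may be present. The 17 further targets, chosen before their values were seen, had a median of 0.56 at percentile 100 (bootstrap interval 0.09 to 0.94). Of these targets, 4 were at least 2-fold higher and 0 lower. These values are given on the main setting only, and Il6 and Nos2 were smaller after normexp. Whether the virus product, the virus preparation or the handling of a single pool lies behind such a response was not tested.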
